A study of Mus musculus with 9 samples.

How the data were processed

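Hindgut RNA of mouse embryos was measured on 9 Affymetrix MOE430 version 2 arrays, 3 per group. The groups, taken from the sample labels, were wild type, Ednrb null and Ednrb NCC null. Ednrb null was homozygous for a lacZ allele of Ednrb. Ednrb NCC null was labelled as lacking Ednrb in NCC cells and titled Ednrb-FLEX, abbreviations the labels do not spell out. Per the labels' protocols, the terminal colon was dissected, RNA was taken up in TRIzol and passed over a column, and biotin-labelled cRNA was made from 150 ng of total RNA. The sample labels give embryonic day 14 and the series text gives 14.5.

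The values deposited by the authors were 1 intensity per probe set and array, made with RMA per the submitters' processing notes. RMA subtracts background, brings the arrays to a common distribution and combines the probes of a probe set. Its version, software and chip definition are not given in the sources used here. RMA values are usually given as log2, but these were on the linear scale, from 5.69 to 61637 over the 9 arrays, and were converted to log2 without a pseudocount. No further normalization or filter was applied. RMA pulls small and dim differences toward 0, and probe sets near the lowest values carry little signal above background, so folds of dim genes understate the change. Arrays have no count depth, and their number limits the precision.

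Of 45101 probe sets, 64 were array controls. The platform's gene table named 1 gene for 34945 probe sets and several for 932, and 9160 probe sets were not in it. For each gene, the brightest probe set (highest mean over the 9 arrays) among those naming that gene alone was used, which gave 18193 genes; 18032 of them were matched by Entrez ID to a RefSeq gene table of the GRCm38.p6 assembly, used here only for names and for which genes neighbour each other, and no symbol needed an update. Probe sets naming several genes or none were tested only as a group. For some named genes the value of another probe set is given beside that of the brightest.

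A linear model with a mean per group was fitted over all 9 arrays with limma 3.58.1 (lmFit and eBayes without trend, not robust) in R 4.3.3. A single estimate of the spread was shared by the groups. The 3 contrasts were Ednrb null against wild type, Ednrb NCC null against wild type, and Ednrb null against Ednrb NCC null. Tests were 2-sided, p-values were adjusted by Benjamini-Hochberg over the 18193 genes of a comparison, and genes with an adjusted p under 0.05 were called. The same 3 wild type arrays served both mutants, so 100 simulations of unchanged groups against shared controls gave the overlap and correlation that arise with no effect.

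Before the data were examined, 29 gene lists were fixed, covering cell types of the gut, cell types that dissection can bring along, signalling families, matrix, position along the gut, cell cycle, handling stress and sex. Of their 530 genes, 499 were measured. Lists were tested with camera of limma at its preset correlation of 0.01, and p-values were adjusted over the 87 tests of lists and comparisons. Of these, 27 passed at the preset correlation, 0 passed with a correlation estimated for each list, and 1 passed with fry, which asks whether a list moves one way and does not compare it with other genes. At an unadjusted p under 0.05, with the estimated correlation, the lists of enteric neural crest, neurons, gut epithelium and Hedgehog, BMP and Wnt signalling each passed in at least 1 comparison. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the members of a list.

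The rule for named genes was also fixed before the data were examined. It takes Ednrb first, then in each comparison the 12 largest rises and 12 largest falls among called genes whose 3 arrays per group did not overlap, then up to 4 members of each list with the smallest p. All members of the endothelin and GDNF families can be named, and unnamed clones are left out unless in the top 3. Genes named outside this rule are said to be so.

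The model was tested on simulated data over 18193 genes with 200 of them changed. Of genes changed 1.5-fold, 67.2% were recovered for Ednrb null against wild type, 62.7% for Ednrb NCC null against wild type and 62.7% between the mutants. At 2-fold the shares were 97.0%, 88.1% and 92.5%, and at 4-fold 100% in each comparison. False calls numbered 9, 4 and 4. A list shifted by -0.5 in simulated data was found in 2 of 2 comparisons with no other list called. Genes were drawn independently there, so this does not show how often lists are falsely called when their members move together.

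Alternatives fixed before the data were examined were centring arrays on their medians, quantile normalization, leaving out the dimmest 40% of genes, fitting only the 2 groups compared, eBayes with trend and robust, array weights, the mean of all probe sets of a gene, all probe sets tested, leaving out each array, an adjusted p under 0.10, a minimum log2 change of 1, and for lists an estimated correlation and fry. After sex-linked levels and RNA quality had been seen, 3 more were added: a covariate for the mean of 3 Y-linked genes, a covariate for the 3' to 5' ratio of the Actb control probe sets, and leaving out wild type 1C and Ednrb NCC null 2 together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The labels used here name no slide or scan batch, so none was tested.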

Results

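Gene expression in the mouse embryonic hindgut was measured on 9 arrays, 3 each for wild type, Ednrb null and Ednrb NCC null embryos. Ednrb encodes endothelin receptor B, which enteric neural crest cells, the precursors of gut neurons and glia, need to colonise the distal gut. Median intensity per array lay between 112 and 116. Across genes, which are not independent replicates, arrays of the same group correlated at Pearson r of 0.9938 to 0.9971. Arrays of different groups correlated at 0.9896 to 0.9944, so the ranges overlapped. Wild type 1C had r = 0.9944 with Ednrb null 29 and 0.9938 with wild type 1D. The labels do not say whether each array came from separate embryos or pools, so p-values measure only the spread between these samples, part of which may be technical. Sex-linked levels argue against the arrays of any group all being repeats of a single sample. Log2 Xist was 6.70 and 14.07 in wild type 1C and 1B and 11.60 and 13.65 in Ednrb null 37 and 29. The mean of the Y-linked genes was 3.74 and 8.80 in Ednrb NCC null 2 and 5.

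Sex-linked transcripts differed between arrays of the same group. Xist, expressed from the inactive X chromosome, had a log2 intensity of 6.70 in wild type 1C and of 11.60 to 14.07 in the other 8 arrays. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty was 3.74 in Ednrb NCC null 2, 5.76 in Ednrb NCC null 6 and 7.65 to 9.38 elsewhere. The sex-linked list passed in no comparison, with adjusted p = 0.974 for Ednrb null against wild type, 0.137 for Ednrb NCC null against wild type and 0.144 between the mutants. The 3' to 5' ratio of the Actb controls, a measure of RNA integrity, was 0.87 ± 0.06 on the log2 scale in Ednrb null, 1.21 ± 0.18 in Ednrb NCC null and 1.18 ± 0.13 in wild type (SD, n = 3). In an exact permutation test, 2-sided, Ednrb null differed from either group at p = 0.1, the smallest p that 3 against 3 arrays allow.

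**Figure D1:**
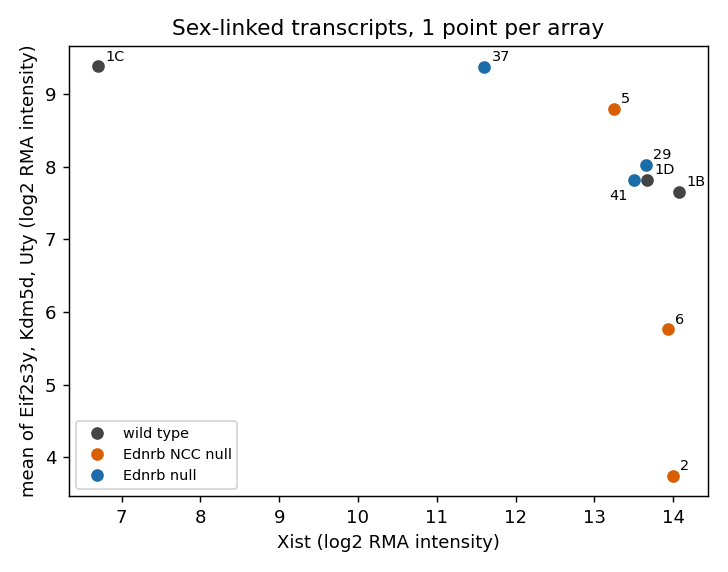
Log2 intensity of Xist against the mean log2 intensity of 3 Y-linked genes, 1 point per array, coloured by group and marked with the replicate label. Wild type 1C lies at 6.70 on the Xist axis, and Ednrb NCC null 2 lies at 3.74 on the Y-linked axis.

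Ednrb itself was read by 3 probe sets. The brightest had a log2 intensity of 11.03 ± 0.07 in wild type, 9.13 ± 0.33 in Ednrb null and 11.17 ± 0.14 in Ednrb NCC null (SD, n = 3). In Ednrb null it fell by 1.89 against wild type (SE 0.14, limma adjusted p = 3.91e-05), which left 27.0% of the wild type intensity. The other probe sets left 32.5% and 32.6%. In Ednrb NCC null the difference from wild type was 0.15 (SE 0.14, adjusted p = 0.653), and the difference between the mutants was -2.04 (adjusted p = 4.49e-05). Whether the probes lie in the deleted part of the gene is not known, and hindgut tissue also holds other cells that express Ednrb, so the level in Ednrb NCC null checks nothing about that label.

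The first comparison asked what differed in the hindgut of Ednrb null embryos from wild type. Of the genes of the enteric neural crest 9 of 18 fell, and of the neuronal genes 5 of 36. Ret, the GDNF receptor of enteric progenitors, was 9.37-fold lower, from 9.59 ± 0.58 to 6.36 ± 0.70 (log2 intensity, SD, n = 3, limma adjusted p = 0.000562). Sox10, a transcription factor of neural crest and glia, was 3.98-fold lower (adjusted p = 0.000481), and Cdh19, a cadherin of glial precursors, 6.60-fold lower (adjusted p = 0.000106). In the plot of crest genes by array, the falls of Ret, Sox10 and Cdh19 were seen in both mutants.

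**Figure D2:**
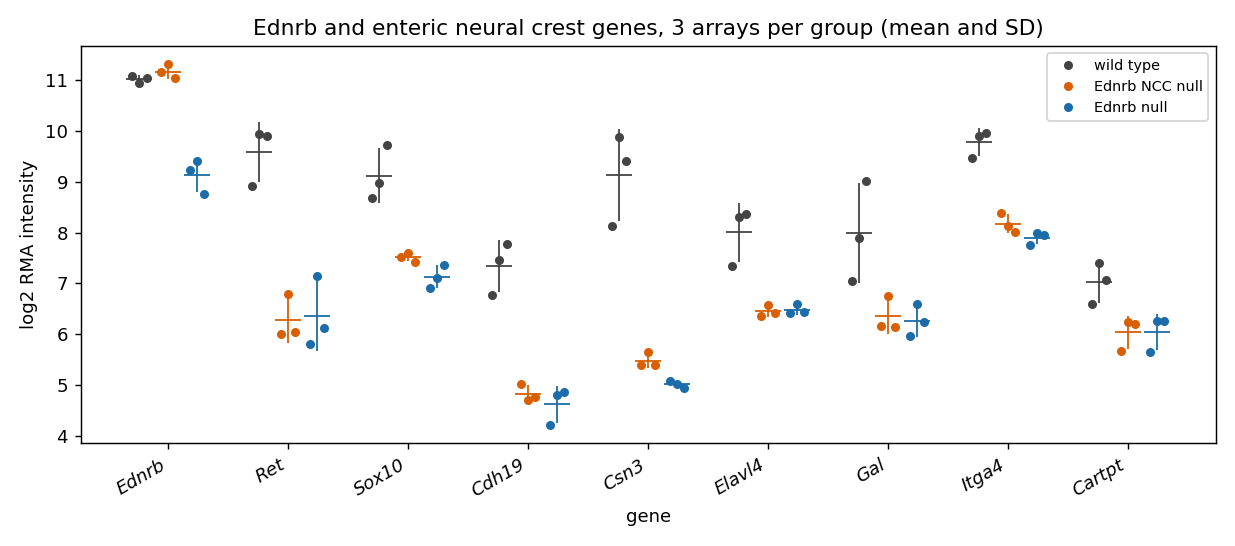
Log2 RMA intensity of Ednrb and of 8 genes of the enteric neural crest or neurons, with 1 point per array and the mean and SD of 3 arrays per group. Ednrb is low in Ednrb null alone, at 9.13, while Ret lies at 6.36 in Ednrb null and 6.28 in Ednrb NCC null against 9.59 in wild type.

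Among the 18 measured members of the enteric neural crest list, which holds Ednrb itself, 9 fell, 0 rose and 9 did not pass in Ednrb null, and 10 fell when adjusted over the list alone. The list median was -0.71 (adjusted p = 1.25e-11, and adjusted p = 0.224 with an estimated correlation). With the Actb ratio, which was lower in Ednrb null, as a covariate the median was -0.40 (adjusted p = 9.00e-10). Besides Ret and Sox10, the adhesion molecule L1cam fell by 1.14 (SE 0.18, adjusted p = 0.00396), with a much dimmer probe set at -0.03. Other probe sets of Ret and Sox10 moved less, at -0.69 for Ret and -0.64 and -0.50 for Sox10. Of 36 neuronal genes 5 fell, 0 rose and 31 did not pass, and 8 fell when adjusted over the list alone (median -0.18, adjusted p = 1.24e-05, and adjusted p = 0.641 with an estimated correlation). Without the dimmest genes the neuronal call was lost (adjusted p = 0.109), and the median was -0.11 without Ednrb null 29, -0.27 without Ednrb null 37 and -0.09 without wild type 1D. Elavl4, an RNA-binding protein of neurons, fell by 1.52 (SE 0.22, adjusted p = 0.00246), and its other 2 probe sets gave -1.81 and -1.25. The glial list had 3 falls among 15 genes, Cdh19, Sox10 and the neuregulin receptor Erbb3 at -0.66 (adjusted p = 0.00832, with a dimmer probe set at -0.08), and 5 adjusted over the list alone (median -0.04, adjusted p = 0.0063, and adjusted p = 0.641 with an estimated correlation). The glial list kept its call with any 1 array left out, but its median was -0.014, 0.012 and -0.15 without Ednrb null 29, 37 and 41, -0.13 without wild type 1C and -0.02 without wild type 1D, and 0.018 with the Actb ratio as a covariate. It was -0.33 over the 7 glial genes left without the dimmest (adjusted p = 0.00043), -0.13 with array weights, -0.13 without wild type 1C and Ednrb NCC null 2 together and -0.0076 with the mean of all probe sets. In the GDNF family 2 genes fell and 1 rose out of 10 (adjusted p = 0.378), and the median of 0.07 and mean of -0.28 differed in sign.

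Some matrix and epithelial genes were also lower in Ednrb null. Of 34 interstitial collagens and matrix glycoproteins 4 fell and 1 rose, and 10 fell and 3 rose when adjusted over the list alone (median -0.27, adjusted p = 6.15e-06, and adjusted p = 0.641 with an estimated correlation). With the Actb ratio as a covariate the matrix median was -0.11 (adjusted p = 0.0455). Col12a1, a fibril-associated collagen, was 2.52-fold lower (adjusted p = 0.000205), with dimmer probe sets at -0.60, -0.15 and -0.09. Of 30 gut epithelial genes 2 fell and 28 did not pass, and 6 fell and 1 rose when adjusted over the list alone (median -0.18, adjusted p = 5.70e-05, and adjusted p = 0.641 with an estimated correlation). The epithelial median was -0.10 without Ednrb null 41. The falls were those of Foxa3 at -1.01 (SE 0.15, adjusted p = 0.00362) and Cdx1 at -1.21 (SE 0.21, adjusted p = 0.00664), transcription factors of gut endoderm. The integrin genes went apart, with Itga4 at -1.88 (adjusted p = 3.85e-05) and Itga9 at 1.95 (adjusted p = 2.92e-06), although the other probe sets of Itga9 gave 0.23 and -0.01 and 4 dimmer ones of Itga4 gave -1.05 to -0.06. The protease gene Adamts1 fell by 0.66 (adjusted p = 0.00853). The embryonic globin gene Hbb-bh1 was 4.45-fold higher (adjusted p = 1.35e-05). Its list of 12 red blood cell genes had 2 rises (median 0.15, adjusted p = 0.0471, and adjusted p = 0.641 with an estimated correlation), a call lost without any 1 of Ednrb null 29, Ednrb null 37, Ednrb NCC null 6 and wild type 1D (adjusted p from 0.0547 to 0.117), and with the Actb ratio as a covariate the median was 0.29. It was lost as well with arrays centred on their medians, array weights or the mean of all probe sets (medians 0.16, 0.15 and 0.12, adjusted p = 0.0567, 0.0554 and 0.0622).

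Of other cell types, the mesothelial list had a median of 0.58 (adjusted p = 0.0174, and adjusted p = 0.652 with an estimated correlation), with none of 10 genes past the threshold. The call was lost without Ednrb null 29 (adjusted p = 0.0548) and without the dimmest genes (adjusted p = 0.0839), and without wild type 1B the median was 0.23. With the Actb ratio as a covariate the median was 0.021 and the test turned direction (adjusted p = 0.725). The skeletal muscle list had a median of -0.25 (adjusted p = 0.00347, and adjusted p = 0.652 with an estimated correlation). Its 1 fall among 22 genes was the cardiac troponin gene Tnnt2 at -1.26 (adjusted p = 0.0056). Other probe sets of Tnnt2 gave -1.51 and 0.18. The list lost its call without wild type 1D (median -0.09, adjusted p = 0.117). Its median was -0.16 without Ednrb null 29, -0.44 without wild type 1C, alone or with Ednrb NCC null 2, and -0.77 over the 4 genes left without the dimmest. The cell cycle list had a median of 0.15 and 1 rise among 24 genes (adjusted p = 0.0492, and adjusted p = 0.743 with an estimated correlation). That call was lost without any 1 of Ednrb null 29, Ednrb null 37, the 3 Ednrb NCC null arrays, wild type 1B and wild type 1D (adjusted p from 0.0521 to 0.274), and the median was 0.098 without Ednrb null 29 and 0.083 without wild type 1B. It was lost as well with the Actb ratio as a covariate (median 0.072, adjusted p = 0.493) and with quantile normalization (median 0.089, adjusted p = 0.247). With the Y-linked level as a covariate the call was lost while the median stayed at 0.15 (adjusted p = 0.0684). The same held for centred arrays (median 0.16, adjusted p = 0.0574), the genes left without the dimmest (0.16, adjusted p = 0.0982), only the 2 groups compared (0.15, adjusted p = 0.0595) and the mean of all probe sets (0.15, adjusted p = 0.233), and over all probe sets the median was 0.12 (adjusted p = 0.188). Endothelial genes (median 0.08, adjusted p = 0.538), macrophage genes (median -0.11, adjusted p = 0.137), cartilage genes (median 0.02, adjusted p = 0.292) and glycolysis genes (median 0.13, adjusted p = 0.144) had no list call. With all probe sets tested, the medians were -0.43 for crest, -0.092 for neurons, -0.025 for glia, -0.12 for epithelium, -0.15 for matrix and -0.13 for skeletal muscle, and these lists kept their calls.

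In all, 482 genes were higher and 435 lower in Ednrb null than in wild type out of 18193, of which 35 and 106 changed at least 2-fold. Which direction held more genes turned with the setting: there were 454 higher and 537 lower with quantile normalization, 479 and 623 without wild type 1C, 436 and 582 without wild type 1C and Ednrb NCC null 2 together, 355 and 365 without Ednrb NCC null 6, 237 and 240 without Ednrb null 29, 218 and 315 without Ednrb null 37 and 205 and 289 without wild type 1B. It turned as well with only the 2 groups compared (267 and 294), all probe sets tested (1131 and 1134), the Actb ratio as a covariate (49 and 82) and, as above, a change of at least 2-fold. Without wild type 1D there were 427 and 285. Arrays of the groups did not overlap for 22.6% of genes, against 10% by chance. Csn3, a casein gene, fell by 4.12 (SE 0.33, adjusted p = 5.09e-05), from 9.14 ± 0.90 to 5.02 ± 0.07, with its other, much dimmer probe set at -0.33. Tmem267 was 12.5-fold lower and Galc, a lysosomal galactosidase, 12.2-fold lower, and other probe sets of Galc gave 0.18 and -0.01. Crh, corticotropin-releasing hormone, lay at 6.67 ± 0.44 in wild type and 3.03 ± 0.22 in Ednrb null, near the lowest intensities of the arrays, so only a bound of at least 12.5-fold is given. These falls are not ranked, as levels this low understate them. Klk13, a kallikrein protease, was 3.68-fold higher and Adat2, a tRNA deaminase subunit, 3.15-fold higher. The count fell to 477 without Ednrb null 29, 533 without Ednrb null 37, 606 without Ednrb null 41 and 494 without wild type 1B. With the Actb ratio as a covariate, added after the ratios were seen, it was 131, and the calls of L1cam, Erbb3, Cdx1, Tnnt2 and Adamts1 were lost (adjusted p = 0.13, 0.147, 0.0507, 0.178 and 0.347).

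The next comparison asked what differed in Ednrb NCC null embryos from wild type. Here 6 of 18 crest genes and 5 of 36 neuronal genes fell, while 4 of 30 epithelial genes and 3 of 18 macrophage genes rose. Ret was 9.92-fold lower, from 9.59 ± 0.58 to 6.28 ± 0.44 (log2 intensity, SD, n = 3, limma adjusted p = 0.000721), with its other probe set at -0.82. Sox10 was 3.04-fold lower (adjusted p = 0.00259, with other probe sets at -0.55 and -0.53) and Cdh19 5.72-fold lower (adjusted p = 0.00033). Lypd8, a surface protein of colon epithelium, was 6.23-fold higher, from 7.37 ± 0.57 to 10.01 ± 0.46 (adjusted p = 0.000721).

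Of the 18 enteric neural crest genes 6 fell and 12 did not pass, and 10 fell when adjusted over the list alone (median -0.52, adjusted p = 6.78e-07, and adjusted p = 0.505 with an estimated correlation). Of 36 neuronal genes 5 fell and 0 rose, and 11 fell and 1 rose when adjusted over the list alone (median -0.28, adjusted p = 1.59e-08, and adjusted p = 0.641 with an estimated correlation). Elavl4 fell by 1.56 (SE 0.22, adjusted p = 0.00315). Gap43, a growth cone protein, fell by 1.09 (adjusted p = 0.0145) and lost its call without Ednrb NCC null 6 (adjusted p = 0.0716). Pou3f3, a transcription factor of neural cells, was 5.69-fold lower (adjusted p = 0.000276), with another probe set at 0.06. The glial list had no call (adjusted p = 0.726), and its median of 0.12 and mean of -0.16 differed in sign. Itga4 fell by 1.60 (adjusted p = 0.000238, with dimmer probe sets at -0.99 to 0.05) and Adamts1 by 0.80 (adjusted p = 0.00396). In the GDNF family 2 genes fell and 8 did not pass (adjusted p = 0.479), and the median of 0.03 and mean of -0.30 differed in sign.

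Of 30 gut epithelial genes 4 rose and 0 fell in Ednrb NCC null, and 15 rose when adjusted over the list alone (median 0.32, adjusted p = 1.46e-05, and adjusted p = 0.641 with an estimated correlation). These included Vil1, a protein of microvilli, at 0.99 (SE 0.21, adjusted p = 0.0225), which lost its call without any 1 of Ednrb NCC null 5, Ednrb NCC null 6 and wild type 1B (adjusted p = 0.089, 0.0987 and 0.0947). Outside the list, the detoxifying enzyme genes Mgst2 and Sult1d1 were 3.84-fold and 3.74-fold higher (adjusted p = 0.000631 and 0.00354). Of 18 macrophage genes 3 rose and 4 rose when adjusted over the list alone (median 0.32, adjusted p = 0.00498, and adjusted p = 0.652 with an estimated correlation). Pf4, a chemokine of platelets and tissue macrophages, rose by 1.09 (SE 0.14, adjusted p = 0.00175). The list lost its call without wild type 1C, the array lowest in Xist (median 0.17, adjusted p = 0.0888), and its median was 0.52 without wild type 1D. Without wild type 1C and Ednrb NCC null 2 together the call was lost as well (median 0.13, adjusted p = 0.188). Mesothelial genes had a median of 0.84, with 1 rise among 10 genes and 6 when adjusted over the list alone (adjusted p = 0.00162, and adjusted p = 0.641 with an estimated correlation). Without wild type 1B the mesothelial median was 0.36. Upk3b, of this list, had a log2 intensity of 6.04 in wild type 1B and 9.30 to 10.46 in every other array. Bnc1 and Muc16 were also lowest in wild type 1B, at 6.71 and 5.03. Much of the mesothelial rise in both mutants thus rests on this array.

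Few signalling and matrix genes passed in Ednrb NCC null. Of 34 genes of Hedgehog, BMP and Wnt signalling 4 fell, also when adjusted over the list alone, and 0 rose (median -0.16, adjusted p = 1.05e-04, and adjusted p = 0.224 with an estimated correlation). The median was -0.10 without Ednrb NCC null 5. Bmp4, a growth factor of gut mesenchyme, fell by 0.55 (SE 0.08, adjusted p = 0.00519). Among matrix genes Col12a1 alone fell, by 0.98 (adjusted p = 0.00218, with dimmer probe sets at -0.47, -0.13 and -0.06), out of 34 (median -0.11, adjusted p = 1.13e-04, and adjusted p = 0.641 with an estimated correlation). The matrix median was -0.19 without Ednrb NCC null 2, -0.063 without Ednrb NCC null 6, -0.26 without wild type 1C, -0.31 without wild type 1C and Ednrb NCC null 2 together and -0.21 with the Y-linked level as a covariate. Endothelial genes had a median of -0.14 with none of 18 past the threshold (adjusted p = 0.0101, and adjusted p = 0.67 with an estimated correlation), a call lost without Ednrb NCC null 6 or wild type 1C (adjusted p = 0.101 and 0.177), with a median of -0.088 without wild type 1C, -0.23 without wild type 1B and -0.096 with the mean of all probe sets. Of 19 genes of glycolysis and hypoxia 2 rose, and 6 when adjusted over the list alone (median 0.16, adjusted p = 0.038, and adjusted p = 0.652 with an estimated correlation), among them Egln3, an oxygen-sensing hydroxylase, by 0.81 (adjusted p = 0.00162, with another probe set at 0.35). That list lost its call without Ednrb NCC null 6 or wild type 1C (adjusted p = 0.0644 and 0.195, the latter with a median of 0.056). The anterior gut list had 1 fall among 12 genes (median -0.08, adjusted p = 0.044, and adjusted p = 0.641 with an estimated correlation), and lost its call without Ednrb NCC null 2 or wild type 1D (adjusted p = 0.176 and 0.117, the latter with a median of 0.0027). With the Y-linked level or the Actb ratio as a covariate both calls were lost while the medians hardly moved, to 0.15 and 0.16 for glycolysis (adjusted p = 0.0793 and 0.0636) and -0.083 and -0.084 for anterior gut (adjusted p = 0.123 and 0.0636). The glycolysis call was lost as well with quantile normalization (median 0.12, adjusted p = 0.0825), without the dimmest genes (0.16, adjusted p = 0.0814) and without wild type 1C and Ednrb NCC null 2 together (0.066, adjusted p = 0.155). That of anterior gut was lost in these settings (medians -0.077, -0.18 and -0.11, adjusted p = 0.0821, 0.058 and 0.0984). It was also lost with array weights (-0.035, adjusted p = 0.0917), the mean of all probe sets (-0.051, adjusted p = 0.127) and all probe sets tested (-0.055, adjusted p = 0.229). With all probe sets tested the medians were -0.34 for crest and 0.17 for macrophages, and these calls were kept. The lists of red blood cells (adjusted p = 0.0983), skeletal muscle (adjusted p = 0.989), cartilage (adjusted p = 0.219) and cell cycle (adjusted p = 0.404) had no call, while Hbb-bh1 was 2.03-fold higher (adjusted p = 0.00336).

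In all, 674 genes were higher and 228 lower in Ednrb NCC null than in wild type, of which 79 and 37 changed at least 2-fold. Without wild type 1C there were 416 and 236, and without wild type 1C and Ednrb NCC null 2 together 354 and 239. Arrays did not overlap for 21.9% of genes, against 10% by chance. Csn3 fell by 3.66 (SE 0.33, adjusted p = 0.000241), with its much dimmer probe set at -0.20. Itga9 was 4.23-fold higher (adjusted p = 7.39e-06), with other probe sets at 0.18 and -0.01. The count fell to 334 without Ednrb NCC null 5, 268 without Ednrb NCC null 6, 352 without wild type 1B and 593 without wild type 1C and Ednrb NCC null 2 together. With the Y-linked level as a covariate it was 536, and the calls of Vil1 and Gap43 were lost (adjusted p = 0.0517 and 0.0795).

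The direct comparison of the mutants asked where Ednrb null and Ednrb NCC null embryos differed. The mutants carry alleles of different construction, which this contrast cannot separate from the cell types that lack the receptor. Of 30 gut epithelial genes 17 were lower in Ednrb null, and none higher. Spink4, a goblet cell protease inhibitor, lay at 7.10 ± 0.18 in Ednrb null and 11.47 ± 0.74 in Ednrb NCC null (log2 intensity, SD, n = 3), a 20.8-fold difference (limma adjusted p = 0.00317). Agr2, a chaperone for mucin folding, was 11.05-fold lower (adjusted p = 0.00224, with a much dimmer probe set at -1.15), and Tff3, a trefoil peptide of mucus, 9.71-fold lower (adjusted p = 0.0045). The wild type mean lay between the mutants for all 3 genes, with a wide spread, as for Spink4 at 9.11 ± 1.64. By array, wild type 1C lay within the range of Ednrb null for all 3 genes, at 7.23 for Spink4, 7.40 for Agr2 and 9.45 for Tff3. Wild type 1B and 1D lay higher, at 9.90 and 10.21 for Spink4.

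**Figure D3:**
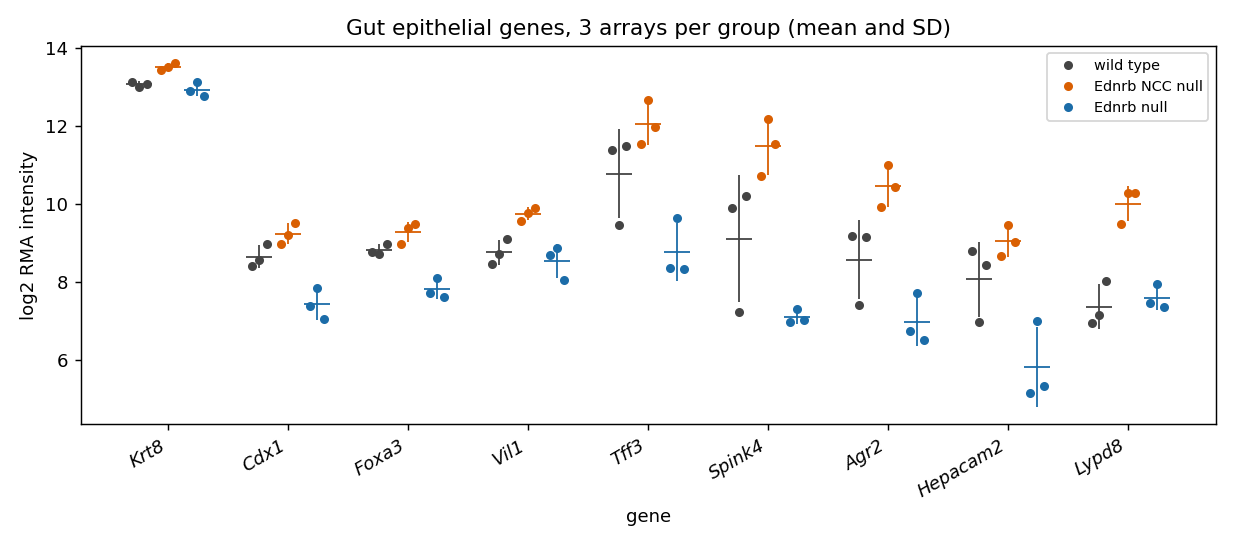
Log2 RMA intensity of 9 genes of gut epithelium, with 1 point per array and the mean and SD of 3 arrays per group. Spink4 lies at 7.10 in Ednrb null, 9.11 in wild type and 11.47 in Ednrb NCC null.

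Of 30 gut epithelial genes 17 fell, 0 rose and 13 did not pass in Ednrb null against Ednrb NCC null, and 22 fell when adjusted over the list alone (median -0.48, adjusted p = 1.10e-12, and adjusted p = 0.641 with an estimated correlation). Cdx1 fell by 1.81 (SE 0.21, adjusted p = 0.00108), Foxa3 by 1.47 (SE 0.15, adjusted p = 0.000654) and the intestinal cadherin Cdh17 by 1.31 (SE 0.20, adjusted p = 0.00418). Outside the list, Hepacam2 was 9.32-fold lower, the actin-severing protein gene Scin 8.42-fold lower and the mucin glycosyltransferase gene Gcnt3 6.11-fold lower, although dimmer probe sets of Gcnt3 gave -0.11 and -0.45. Gcnt3 was dim in Ednrb null, at 4.38 to 4.60, so its fold may be understated. The Actb ratio differed between these groups by -0.34. With that ratio as a covariate the list stayed past the threshold (median -0.57, adjusted p = 3.09e-12), but Spink4 went from -4.38 (SE 0.63) to -4.46 (SE 1.09, adjusted p = 0.0869), and the calls of Agr2, Tff3, Hepacam2, Scin and Gcnt3 were lost as well (adjusted p from 0.0537 to 0.0989).

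Of 18 macrophage genes 4 fell in Ednrb null against Ednrb NCC null, and 10 when adjusted over the list alone (median -0.49, adjusted p = 6.84e-06, and adjusted p = 0.641 with an estimated correlation). Pf4 fell by 0.81 (SE 0.14, adjusted p = 0.0059). Of 18 endothelial genes 3 rose, and 5 when adjusted over the list alone (median 0.19, adjusted p = 0.00378, and adjusted p = 0.652 with an estimated correlation). Robo4, a receptor of blood vessels, rose by 0.60 (adjusted p = 0.0108) and lost its call without Ednrb NCC null 6 (adjusted p = 0.0514). The skeletal muscle list had 3 falls among 22 genes (median -0.27, adjusted p = 0.00768, and adjusted p = 0.67 with an estimated correlation). Of these genes 18 lay below 0 and 4 above. Tnnt2 fell by 1.48 (adjusted p = 0.0028, with other probe sets at -1.66 and -0.06), while Ckm and Tnni2 were at -0.03 and -0.06. Tnnt2 is the cardiac form, so these falls need not come from skeletal muscle. The list median was -0.41 with the Actb ratio as a covariate, -0.90 over the 4 genes left without the dimmest and -0.15 with all probe sets tested. Its call was lost without Ednrb null 29 or Ednrb NCC null 5 (adjusted p = 0.0548 and 0.0851). In the glial list 2 of 15 genes fell, and 3 when adjusted over the list alone (median -0.13, adjusted p = 0.0129, and adjusted p = 0.641 with an estimated correlation), with a median of -0.07 without Ednrb null 37 and -0.23 without Ednrb null 41. The glial median was -0.36 over the 7 genes left without the dimmest, -0.072 with the mean of all probe sets and -0.051 with all probe sets tested. The cell cycle list had 2 rises among 24 genes and 3 when adjusted over the list alone (median 0.11, adjusted p = 0.0063, and adjusted p = 0.67 with an estimated correlation), and lost its call without Ednrb null 29 (median 0.07, adjusted p = 0.0616) and with the mean of all probe sets (median 0.091, adjusted p = 0.0554).

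Some signalling and cartilage genes were higher in Ednrb null than in Ednrb NCC null. Of 34 genes of Hedgehog, BMP and Wnt signalling 4 rose and 1 fell, and 5 rose and 1 fell when adjusted over the list alone (median 0.11, adjusted p = 0.0237, and adjusted p = 0.641 with an estimated correlation). The list call was lost without Ednrb NCC null 6 (median 0.082, adjusted p = 0.0679) and without the dimmest genes (median 0.15, adjusted p = 0.0656). The median was 0.17 without Ednrb null 29, 0.21 without Ednrb NCC null 2, alone or with wild type 1C, 0.18 with array weights, and 0.19 and 0.21 with the Y-linked level and the Actb ratio as covariates. Bmp4 rose by 0.61 (SE 0.08, adjusted p = 0.00266). Of 15 cartilage genes 4 rose, also when adjusted over the list alone (median 0.07, adjusted p = 0.044, and adjusted p = 0.641 with an estimated correlation). Col2a1, the main collagen of cartilage, rose by 1.11 (SE 0.14, adjusted p = 0.00203), while the list lost its call without Ednrb null 41, Ednrb NCC null 2 or wild type 1B (adjusted p = 0.117, 0.16 and 0.0517), with a median of 0.036 without Ednrb null 41. Its call was lost as well with array weights (median 0.06, adjusted p = 0.106), the mean of all probe sets (0.073, adjusted p = 0.0927) and without wild type 1C and Ednrb NCC null 2 together (0.08, adjusted p = 0.0854). The cartilage median was 0.69 over the 6 genes left without the dimmest (adjusted p = 0.01) and 0.15 with all probe sets tested. Crest genes (median -0.10, adjusted p = 0.0925), neurons (median 0.05, adjusted p = 0.238), matrix genes (median -0.01, adjusted p = 0.434), mesothelium (median -0.23, adjusted p = 0.341), glycolysis (median -0.03, adjusted p = 0.454) and anterior gut (median 0.04, adjusted p = 0.548) had no list call. Red blood cell genes had none either (adjusted p = 0.54), and their median of -0.01 and mean of 0.13 differed in sign, while the embryonic globin genes Hbb-bh1 and Hba-x were 2.19-fold and 2.21-fold higher (adjusted p = 0.00184 and 0.00205).

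**Figure D4:**
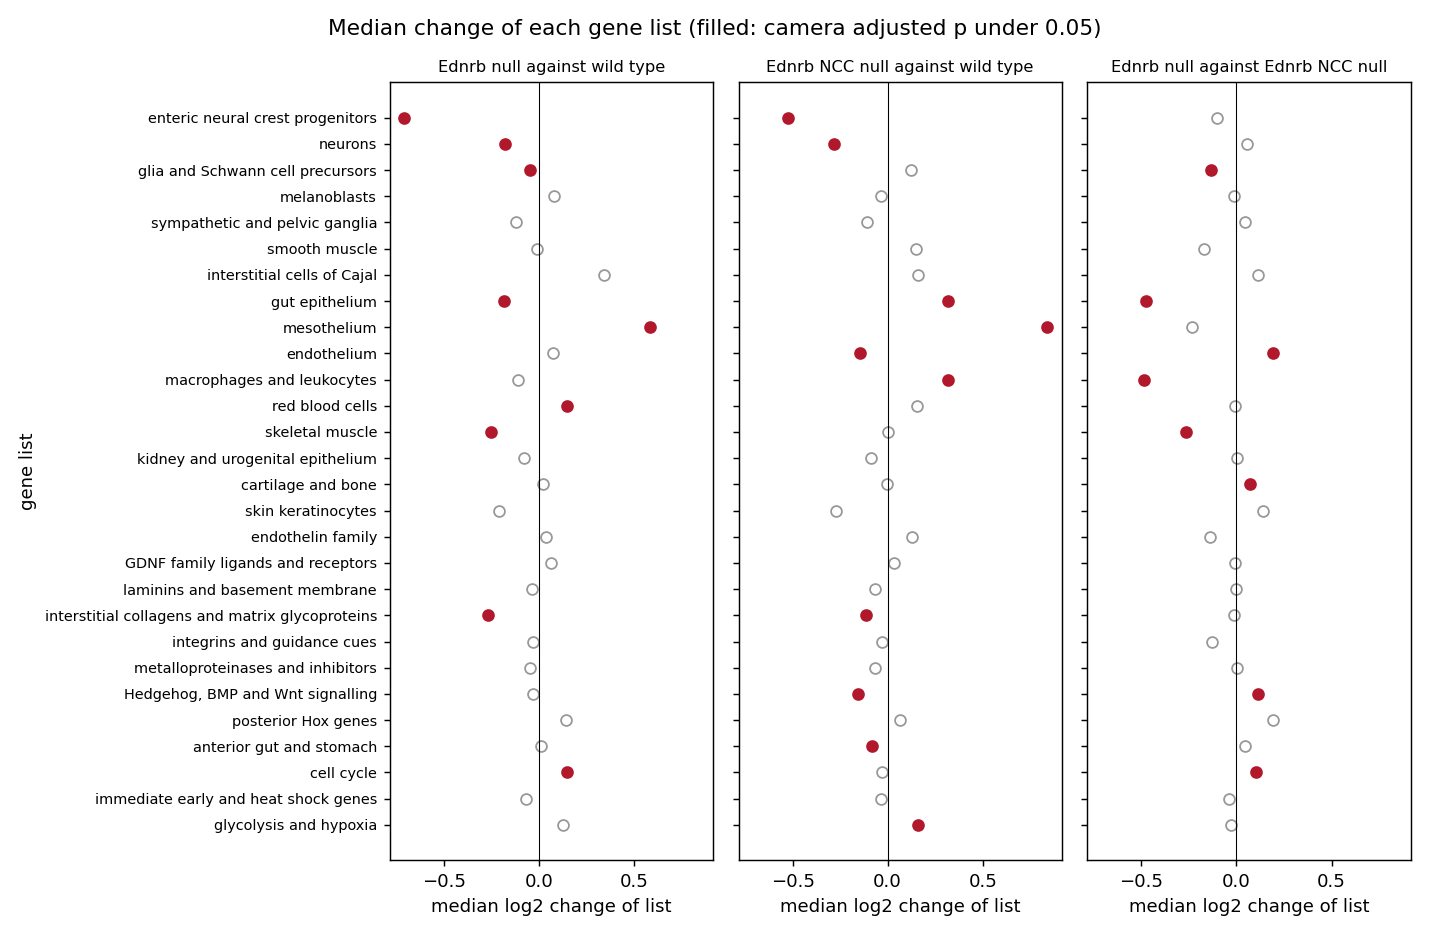
Median log2 change of each gene list except the sex-linked one in the 3 comparisons, on the same axis, with filled points for lists with a camera adjusted p under 0.05. The gut epithelium list lies at -0.18, 0.32 and -0.48, and the enteric neural crest list at -0.71, -0.52 and -0.10.

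In all, 376 genes were higher and 811 lower in Ednrb null than in Ednrb NCC null, of which 22 and 160 differed at least 2-fold. More genes were lower than higher in every setting. Without Ednrb null 37 there were 217 higher and 770 lower, without Ednrb NCC null 2 439 and 636, and with array weights 995 and 1326. Arrays did not overlap for 24.2% of genes, against 10% by chance. Scn3a, a neuronal sodium channel, was 3.12-fold higher, with a dimmer probe set at 0.07, and Inhba, an activin subunit, 2.22-fold higher, with a dimmer probe set at -0.14. For Zfp945 the probe set used gave 1.79 and another gave -2.50, so no direction is given for the gene. The count fell to 521 without Ednrb null 29, 587 without Ednrb null 41, 613 without Ednrb NCC null 5 and 507 without Ednrb NCC null 6. With the Y-linked level as a covariate it was 677 and with the Actb ratio 215, while with array weights it was 2321. With the Actb ratio the calls of Robo4, Tnnt2, Bmp4 and Hbb-bh1 were lost (adjusted p = 0.138, 0.0888, 0.127 and 0.106), as were those of the endothelial, glial, cartilage and cell cycle lists (adjusted p = 0.0652, 0.0823, 0.0823 and 0.309), whose medians of 0.19, -0.13, 0.073 and 0.11 were then 0.14, -0.13, 0.073 and 0.11. With the Y-linked level the glial, cartilage and cell cycle calls were lost (adjusted p = 0.0684, 0.0684 and 0.0741), with medians of -0.13, 0.13 and 0.11.

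Genes called in both mutants against wild type numbered 283 in the same direction, 159 higher and 124 lower, and 9 in opposite directions. Ret, Sox10, Cdh19, Csn3, Elavl4, Itga4 and Col12a1 were lower in both, and Itga9 and Hbb-bh1 higher in both. Of the 283 genes, 20 also differed between the mutants, as Hbb-bh1 did. Of 625 genes called in Ednrb null alone, 293 differed between the mutants, and of 610 called in Ednrb NCC null alone, 282 did. Independent lists of these sizes would share 17.9 higher and 5.45 lower genes, and simulations with no effect gave a mean of 0.01 and at most 1. With no effect few genes are called at all, so the simulated overlap was bound to be small. It does not show how much overlap the shared controls add among real calls. Across genes, the log2 changes of the mutants had a Pearson r of 0.427 and Spearman rho of 0.407, while simulations with no effect gave a mean r of 0.499 and at most 0.545. The covariance was 0.0275 against 0.00926 simulated, a difference of 0.0183, and 65.6% of genes had the same sign against 66.7% simulated. Genes were drawn independently in these simulations too. Where genes move together between arrays the simulated range may be too narrow, so these differences do not decide whether the mutants share effects. The 3 wild type arrays were too few to split, and part of the excess overlap may come from these shared controls. The shared count fell to 171 without Ednrb null 29, 181 without Ednrb null 37, 155 without Ednrb NCC null 5, 133 without Ednrb NCC null 6 and 157 without wild type 1B. In it more genes were lower than higher without Ednrb null 37 (96 and 85), Ednrb NCC null 6 (67 and 66), wild type 1B (94 and 63) or wild type 1C (156 and 146), without wild type 1C and Ednrb NCC null 2 together (136 and 109), with all probe sets tested (390 and 332), with the Actb ratio as a covariate (41 and 27) and at a change of at least 2-fold (27 and 13), and without Ednrb NCC null 2 there were 103 higher and 100 lower.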

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

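In this part, the test of a smaller share of epithelium and the fit with the Actb ratio were chosen after results had been seen, and the prediction for RNA quality was written after the gene counts of that fit were known but before the value of the list. The results below stood out because the direct contrast of the 2 mutants passed its threshold, so that their effects against wild type differed. All log2 differences are Ednrb null minus Ednrb NCC null.

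Among gene lists, the median differed by -0.48 for gut epithelium, -0.49 for macrophages and leukocytes, -0.27 for skeletal muscle and -0.13 for glia. It differed by 0.19 for endothelium, 0.11 for Hedgehog, BMP and Wnt signalling, 0.11 for cell cycle and 0.073 for cartilage and bone. None of these list differences passed with an estimated correlation (adjusted p = 0.641 to 0.67), where gut epithelium and the signalling list had unadjusted p = 0.041 and 0.0306.

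Ednrb differed by -2.04. Of the genes with the largest changes against wild type, several were lower in Ednrb null. The differences were -3.47 for Agr2, -2.88 for Ugt2b34, -2.42 for Lypd8, -2.03 for Pglyrp1 and -1.80 for Sult1d1. They were -1.68 for Gsdmc2, -1.59 for Eps8l3, -1.59 for Prss32, -1.25 for Phgr1 and -1.02 for Mgst2. Other genes lower in Ednrb null were Tmem267 at -3.13, Taf15 at -3.10, Zfp874a at -2.84, Crh at -2.80 (a lower bound in size, since Crh lay near the lowest intensities in Ednrb null), Zfp429 at -2.50, Pcdhb9 at -2.33, Galc at -2.19 and Mid1 at -1.98. Tmem267 and Zfp874a were also dim in Ednrb null, at 4.25 to 4.98 and 4.53 to 4.88, so their differences may be understated. Dimmer probe sets gave 0.42 for Taf15, -0.02 and -0.14 for Mid1, 0.19 and -0.06 for Galc and -1.15 for Agr2. Genes higher in Ednrb null were Otor at 1.46, Abcb1b at 1.14, Hbb-bh1 at 1.13, Adat2 at 1.10, A330076H08Rik at 0.75 and Klk13 at 0.62. Dimmer probe sets gave 0.12 for Abcb1b and 0.20 for A330076H08Rik.

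Probe sets that name several genes or none stood out as signal outside the genes compared in the report. Of 10092 such probe sets, 576 passed for Ednrb null against wild type, 351 for Ednrb NCC null against wild type and 415 between the mutants.

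The pattern weighed here is the lower level of gut epithelial genes in Ednrb null than in Ednrb NCC null. A smaller share of epithelium as the whole cause would move its transcripts alike if only epithelium made them and arrays read folds equally. Epcam, Cdh1, Krt8 and Krt18 had a median of -0.50, and 6 of 30 members lay below it with their whole 95% interval. These were Vil1, Cdx1, Tff3, Foxa3, Ihh and Cdh17. In the other direction, 3 members lay above 0, Cldn3 at 0.26, Cldn6 at 0.28 and Prom1 at 0.22. The members thus did not move alike. This goes against a loss of all epithelium alike as the whole cause only under those conditions, which were not tested. The error of that median was not counted either. A smaller share of some epithelial cell types alone was not tested. Epcam, Cdh1, Krt18, Ihh, Cldn6 and Prom1 lie outside the rule for named genes. With the Actb ratio as a covariate the list median was 119.7% of its size and passed. This met the bound set against RNA quality as the whole cause, although Spink4 went from -4.38 (SE 0.63) to -4.46 (SE 1.09) and lost its call because its error grew. The ratio was at most 0.90 in Ednrb null and at least 1.03 in every other array. The fit thus rests on the spread within groups and cannot set RNA quality apart from the group, so RNA quality stays open. A younger stage of the Ednrb null embryos stays open: the median of 6 genes that decline with embryonic age was 0.0993, too close to 0 to decide, with 4 of them above 0. Hmga2, outside the rule for named genes, was at 0.64 (adjusted p = 0.0174), and its other probe sets at 0.59, 1.11 and 0.71. Trim71, also outside the rule, lay at -0.41 (adjusted p = 0.217). The embryonic globin genes Hbb-bh1 and Hba-x, higher in Ednrb null as given above, were not part of this test. Their red blood cell list had no call (adjusted p = 0.54). A difference in the stretch of colon dissected stays open too. The list of posterior Hox genes had a median of 0.19 with 11 of 15 genes above 0 (adjusted p = 0.0925). In it 2 genes rose past the threshold, Hoxd11 at 0.53 among them, and 1 fell, Hoxb9 at -0.56. The anterior gut list had a median of 0.04 (adjusted p = 0.548), and together these values decide for neither answer. An effect of the genotype stays open, as it was not tested apart from the groups.

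The counts of called genes were set against the other splits of each 6 arrays into 3 and 3. In each comparison 1 of 10 splits, the real one, gave as many genes, and 10 splits are too few for a share under 0.05. The real counts were 917, 902 and 1187, and the highest of the other splits was 0 in each.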

How the results depend on the processing

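The covariates for the Y-linked level and the Actb ratio, and leaving out wild type 1C with Ednrb NCC null 2, were added after the data were seen. No paired analysis was possible because the groups share no replicate numbers. Groups of 3 are too small for a test of outlying arrays. Signal over background limits dim genes, whose changes are understated.

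Called genes numbered 917 for Ednrb null against wild type, 902 for Ednrb NCC null against wild type, 1187 between the mutants and 283 in both mutants. Leaving out 1 array gave 477 to 1102, 268 to 1099, 507 to 1309 and 133 to 302, with fewer arrays. Looser and stricter thresholds gave 1459, 1550, 1838 and 484 at an adjusted p under 0.10, and 141, 116, 182 and 40 at a log2 change of at least 1. Testing all probe sets, which are more numerous, gave 2265, 1611, 1984 and 722. With only the 2 groups compared, and so fewer arrays, Ednrb null against wild type gave 561 and both mutants 175. Array weights gave 2321 between the mutants, and the cause was not tested. The Y-linked covariate gave 536 for Ednrb NCC null, 677 between the mutants and 177 in both, and leaving out the pair of arrays 593 for Ednrb NCC null. The Actb covariate gave 131 for Ednrb null, 215 between the mutants and 68 in both. The cause was not tested for either covariate. The Actb ratio was lower in every Ednrb null array than in any other array, and errors grew in that fit, as for Spink4. Its lower counts thus neither show nor exclude an effect of RNA quality.

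The correlation of the mutants' changes, 0.427, was 0.353 to 0.525 with 1 array left out, 0.364 without the dimmest genes, 0.536 over all probe sets and 0.202 with the Actb covariate, and the cause was not tested. Of list tests, 27 passed at the preset correlation, 0 with an estimated correlation, which allows for members moving together, and 1 with fry.

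Directions turned in a few cases, and the cause was not tested unless given. With the Actb covariate, the mesothelium list for Ednrb null against wild type was at 0.021 with its test turned, the sex-linked list was at -3.28, and the value for Uty, Ednrb null against wild type, was -3.03. With the mean of all probe sets, which adds dimmer ones, Zfp945 was at -0.18 between the mutants, Spry2 at 0.31 in Ednrb null and 0.29 in Ednrb NCC null, and Lamb1 at 0.43 in Ednrb NCC null. Over all settings, called results of named genes kept direction and call in 2837 cases, lost the call in 572 and turned in 1, and called lists did so in 474, 119 and 1. Uncalled named genes passed in 236 cases and uncalled lists in 69.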

Other observations

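The tests of neighbouring genes, of differing probe sets and of embryos of both sexes, and the fit with the Y-linked level, were chosen after results had been seen. Some smooth muscle genes were lower in Ednrb null than in Ednrb NCC null. Cnn1, calponin of contractile smooth muscle, fell by 1.01 (SE 0.13, limma adjusted p = 0.00189) and Tagln, an actin-binding protein of smooth muscle, by 0.92 (SE 0.16, adjusted p = 0.00697). Of 22 smooth muscle genes 2 fell and 1 rose, and 8 fell and 3 rose when adjusted over the list alone. The list did not pass between the mutants (adjusted p = 0.0578), in Ednrb null against wild type (adjusted p = 0.205) or in Ednrb NCC null against wild type (adjusted p = 0.294). The list of interstitial cells of Cajal, the pacemaker cells of the gut, had adjusted p = 0.063 and a median of 0.34 in Ednrb null against wild type, 0.292 in Ednrb NCC null and 0.404 between the mutants. Hand1, a transcription factor of the ganglia list, rose by 0.93 in Ednrb null (SE 0.14, adjusted p = 0.00326). The list of sympathetic and pelvic ganglia had adjusted p = 0.0975 in each mutant and 0.856 between them, where its median of 0.05 and its mean of -0.0029 differed in sign.

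Of 15 posterior Hox genes 2 were higher and 1 was lower past the threshold in Ednrb null than in Ednrb NCC null. Hoxd11 was among the higher, at 0.53 (adjusted p = 0.00759), and Hoxb9 was the lower, at log2 -0.56 (adjusted p = 0.00783). Their list had adjusted p = 0.17, 0.757 and 0.0925 in the order Ednrb null against wild type, Ednrb NCC null against wild type and Ednrb null against Ednrb NCC null, which holds for the values that follow, and in Ednrb NCC null its median of 0.06 and mean of -0.0021 differed in sign. The endothelin family had adjusted p = 0.54, 0.418 and 0.205, with Ednrb itself as the 1 member that fell in Ednrb null, where the median of 0.04 and mean of -0.17 differed in sign. Integrins and guidance cues had adjusted p = 0.088, 0.479 and 0.185, laminins and basement membrane 0.115, 0.144 and 0.893, and metalloproteinases 0.211, 0.0944 and 0.634. Melanoblasts had 0.856, 0.629 and 0.858, kidney and urogenital epithelium 0.489, 0.522 and 0.908, and skin keratinocytes 0.144, 0.127 and 0.893. For melanoblasts the median and mean were 0.08 and -0.0089 in Ednrb null against wild type and -0.01 and 0.0094 between the mutants, and for kidney between the mutants both were 0.0041 and 0.0043 while the test pointed down. Immediate early and heat shock genes had 0.0798, 0.15 and 0.726, and the GDNF family had 0.908 between the mutants, with a median of -0.0077 and a mean of 0.02. The Hedgehog, BMP and Wnt list in Ednrb null had adjusted p = 0.205, and the anterior gut list 0.155, with a median of 0.01 and a mean of -0.15.

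Several large changes were seen by 1 probe set of a gene. A candidate explanation is a sequence variant or transcript form read by that probe set alone. Of 29 called genes with a log2 change of at least 1 and another probe set of like brightness, 7 (24.1%) had the other probe set move less than 1/3 as far. This met the bound of 20% set for the explanation over all comparisons together. Taken singly, 4 of 15 (26.7%) did so in Ednrb null, 1 of 11 (9.09%) in Ednrb NCC null and 3 of 15 (20%) between the mutants, so these few genes leave the explanation open. Itga9 and Galc were not among these genes, as their other probe sets were dimmer. Called genes also lay side by side more often than in 10000 random placements, with 59 pairs against a median of 42 for Ednrb null (permutation p = 0.0066), 55 against 41 for Ednrb NCC null (permutation p = 0.016) and 88 against 71 between the mutants (permutation p = 0.021), which goes with inherited segments of another mouse strain, while neighbours regulated together would give such an excess as well. Of the 40 nearest genes around Ednrb, 4 (10%) were called in Ednrb null, 2 (5%) in Ednrb NCC null and 1 (2.5%) between the mutants, against 5.04%, 4.96% and 6.52% of all genes.

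Sex-linked levels differed within groups. In 6 of 9 arrays both Xist and the Y-linked mean lay within 3 log2 units of their highest array, which goes with RNA of embryos of both sexes in different shares, while maternal tissue stays open. Whether such shares account for the calls between the mutants stays open, since 50.4% of those calls were kept with the Y-linked level as a covariate, between the bounds set for either answer.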
